A study of Tupaia belangeri with 8 samples.

How the data were processed

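Small RNA was sequenced in 8 samples of primary neurons of neonatal tree shrew (Tupaia belangeri), 4 labelled PBS and 4 labelled METH. Per the labels' protocols, cells grew in Neurobasal-A medium with 15% fetal bovine serum and B-27 supplement. METH wells received 5 µl of a methamphetamine stock given as 100 mmol in 995 µl of medium, control wells received medium alone after a PBS rinse, and cells were collected after 24 h. Libraries were made by joining an adapter to each end of the RNA, copying it into cDNA, amplifying by PCR and selecting fragments by size on a gel, per the labels' protocols. The protocols mention no molecular identifiers, so the intervals of shares, of pooled read counts and of counts of 0 cover counting error only, while the intervals of log2 fold changes include the spread between libraries. No label says whether the 4 samples of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

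The authors deposited 1 table of 384 miRNAs, of which 159 carry a known name and 225 are predicted and carry a number instead. Its columns hold raw read counts and TPM per library, per the file headers. The deposited TPM values equal the read count divided by the library's total over the listed miRNAs and scaled by 1 constant factor, with no length term (largest difference 4.51e-05), so they add no information on depth. The aligner, the miRNA reference, the prediction tool and the genome build are not given in the sources used here. The table gives names without sequence or position, so no genomic coordinates were used here, and reads that could be shared between near-identical family members (let-7, miR-30, miR-29) or between a predicted and a known miRNA cannot be separated.

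Groups were taken from the sample titles. The comparison of METH with PBS used edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, the filterByExpr filter (minimum count 10, minimum total 15), and the quasi-likelihood F test with robust estimation and Benjamini-Hochberg adjustment at 0.05. The filter kept 166 miRNAs (113 known, 53 predicted), which held 99.8% or more of each library's counts after rounding. Normalised CPM are counts divided by the TMM-scaled library size, and log2 fold changes are METH over PBS. The standard error was derived from the F statistic, and intervals are 95% intervals with the test's degrees of freedom. A miRNA below the filter has its log2 fold change from the same model fitted with no filter, and this is stated where such a value is given. The design, the miRNA lists and the rule for named miRNAs were fixed before the data were examined.

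The lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between miRNAs, where at least 3 members were tested, and again with an estimated correlation and with fry. They cover neuron-enriched, oligodendrocyte-associated, astrocyte-associated, microglia and leukocyte, fibroblast and smooth muscle, endothelial, epithelial, muscle, and blood and serum miRNAs, the miR-17-92 and paralogous clusters, p53-induced miRNAs, the let-7 and miR-15/16 families, inflammation and stress miRNAs, miRNAs of the psychostimulant and of the dopaminergic neuron literature, and the imprinted DLK1-DIO3 cluster. Predicted miRNAs were set against known ones in the same way. The 5p to 3p arm ratio, as log2 of counts with 0.5 added, was tested with limma. Library measures (total count, share of the most abundant miRNA, share of predicted miRNAs, and effective number, the exponential of the Shannon entropy of the count shares) were compared with exact two-sided permutation tests over 70 splits, whose smallest possible p is 0.0286. Shares have 95% Wilson intervals of at most 0.151 percentage points either way.

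The named miRNAs are the one in the series title and every miR-146 family member, the 10 with the smallest edgeR p because none passed the threshold, the 5 most abundant, and up to 4 members of each list with the smallest p, in all 56. Where another miRNA is named, it was chosen after its values were seen, and the text says so.

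The test was checked on simulated counts for the 166 miRNAs of this comparison, in 20 data sets with 60 changed miRNAs each. With dispersions as estimated here (median 0.53), 2.75% of miRNAs changed 2-fold, 24.8% of those changed 4-fold and 67% of those changed 8-fold were called, and 0.613% of unchanged ones. With a dispersion of 0.05, the shares were 93%, 100% and 100%, with 1.84% of unchanged ones called. With no changed miRNA, 0 of 3320 simulated tests were called at the estimated dispersions and 0.0301% at a dispersion of 0.05. The simulated miRNAs varied independently of each other, while in the data 1 principal component held 65.7% of the variance. The shares called therefore apply to independent miRNAs and may not hold for these libraries.

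The alternatives were DESeq2 1.42.0, other scalings (DESeq2 size factors, upper quartile, total counts), no filter or a mean count of at least 10 or 50, a replicate block, limma on log2 TPM with pseudocounts of 1 and 0.1, another threshold, the most abundant miRNA left out, fitting without robust estimation, and each library left out in turn. After the data were seen, 3 further alternatives were added, which leave out both libraries numbered 4, leave out PBS 1, PBS 3 and METH 3, or include 1 surrogate variable from sva 3.50.0. No library was left out of the main comparison. Chi-square per degree of freedom between libraries of a group was at least 368, far above sampling noise, so no library was treated as a duplicate.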

Results

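miRNA levels were measured by small RNA sequencing in primary neurons isolated from neonatal tree shrews, a small mammal close to primates, after 24 h with methamphetamine (METH, a psychostimulant that releases dopamine) or without it (PBS). Each group had 4 libraries. The series asks which miRNAs accompany METH-induced neuronal damage, and its title names a predicted miRNA, novel_146, together with Tfdp2, a dimerisation partner of the E2F transcription factors. Total miRNA counts in the PBS libraries numbered 1 to 4 were 526031, 778888, 388419 and 7334789. Those of the METH libraries were 642982, 680580, 339243 and 6702946. The range was 21.6-fold, and mean totals did not differ between groups beyond the spread (exact permutation p = 0.714).

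**Figure D1:**
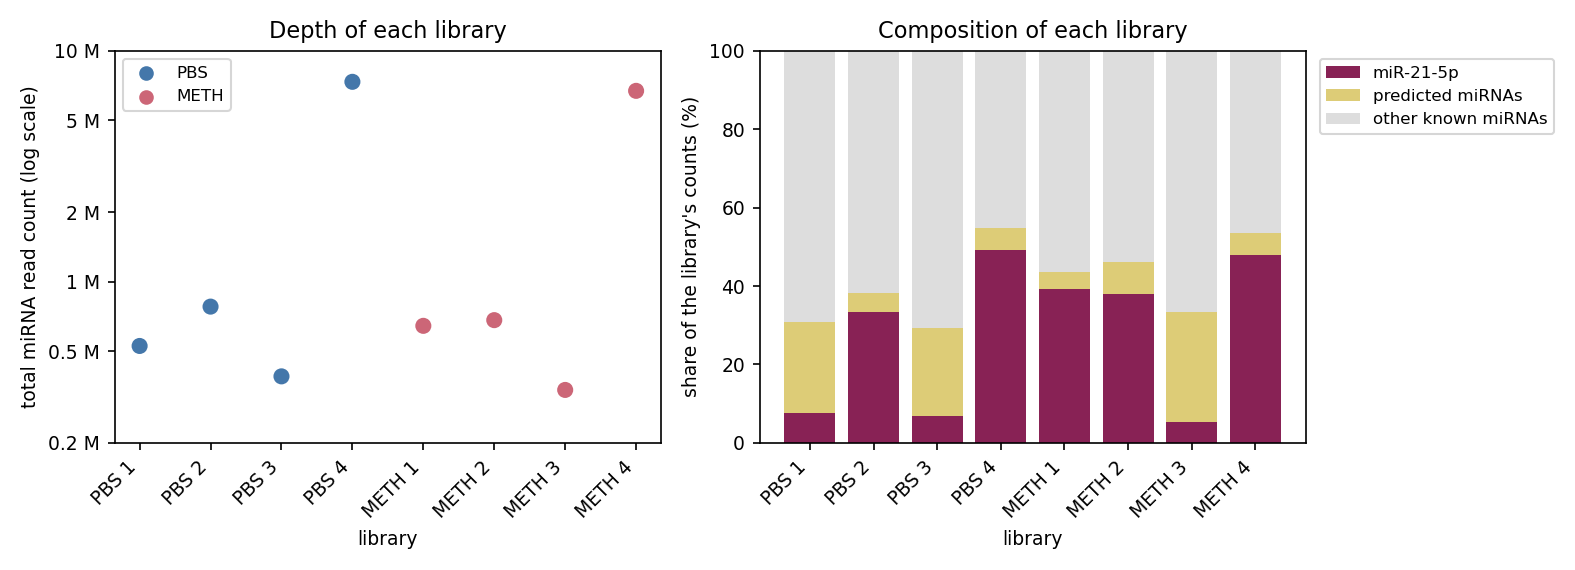
Total miRNA read count of each library on a log axis (M, mega), and the share of its counts in miR-21-5p, in predicted miRNAs and in other known miRNAs (%). miR-21-5p took 7.53% of the counts in PBS 1, 6.95% in PBS 3 and 5.26% in METH 3, and between 33.5% and 49.3% in the other 5 libraries.

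miR-21-5p, which is induced by injury and stress in many cell types, was the most abundant miRNA, with 24.3% ± 20.8 (SD, n = 4) of the counts in PBS and 32.6% ± 18.7 (SD, n = 4) in METH (exact permutation p = 0.571). Of the other 4 of the 5 most abundant miRNAs over both groups, miR-148a-3p held 5.27% ± 6.14 in PBS and 5.74% ± 4.84 in METH (n = 4 each, exact permutation p = 0.971). let-7i-5p held 5.06% ± 1.5 and 4.05% ± 0.654 (exact permutation p = 0.314), miR-99a-5p held 4.65% ± 2.35 and 4.56% ± 1.72 (exact permutation p = 0.886), and the predicted miRNA novel_2 held 6.14% ± 4.71 and 4.84% ± 4.75 (exact permutation p = 0.914). The effective number of miRNAs was 23.3 ± 12 in PBS and 18.7 ± 8.84 in METH (n = 4 each, exact permutation p = 0.6). Predicted miRNAs together held 14.0% ± 10.2 of the counts in PBS and 11.6% ± 11.1 in METH (exact permutation p = 0.914). In edgeR, miR-148a-3p had a log2 fold change of −0.02 (SE 1.26; −0.78 without METH 1 and 1.49 without PBS 2), miR-99a-5p had 0.25 (SE 0.60; −0.19 without METH 1 and 0.63 without PBS 2) and novel_2 had 0.10 (SE 0.66; −0.72 without METH 3 and 0.33 without METH 4). The adjusted p over the total, the top share, the predicted share and the effective number was 0.914 for each.

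PBS 1, PBS 3 and METH 3 stood apart from the other 5 libraries. On the first principal component, with 65.7% of the variance, they lay at −14.64, −13.03 and −18.64, and the others between 6.34 and 11.94. miR-143-3p, a smooth muscle and fibroblast miRNA, was at 1890, 4925 and 1117 normalised CPM in PBS 1, PBS 3 and METH 3, and between 24319 and 80855 in the others. miR-148a-3p was at 6038, 4375 and 2204 normalised CPM in them, and between 48252 and 213372 in the others. Neuron-enriched miRNAs did not all follow this division. miR-9-5p, a regulator of neurogenesis, was at 56334 in PBS 1 and 64267 in METH 3 but at 6507 in PBS 3, and miR-128 lay between 1432 and 3538 over the 8 libraries. The first component did not separate PBS from METH (exact permutation p = 0.943).

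**Figure D2:**
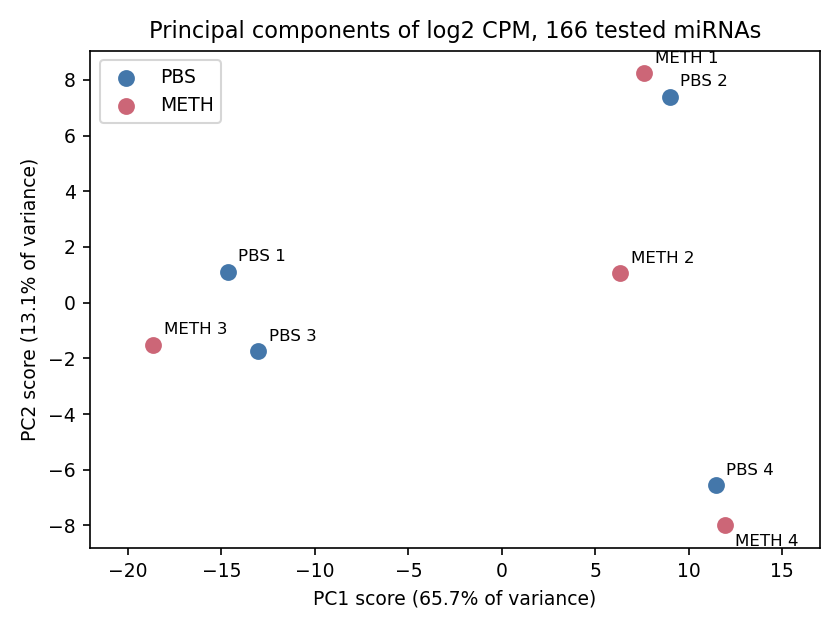
Scores of the 8 libraries on the first (65.7% of variance) and second (13.1% of variance) principal components of log2 CPM, with 1 point per library. PBS 1, PBS 3 and METH 3 lie at −13.03 or lower on the first component, and both groups have libraries on either side.

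Between METH and PBS, the lowest p belonged to miR-122-5p, a liver miRNA also found in serum, with 92.7 ± 81.3 normalised CPM in PBS and 17.5 ± 18.0 in METH (SD, n = 4; log2 fold change −2.43, SE 1.17, edgeR adjusted p = 0.999), and lay below the PBS mean in 4 of 4 METH libraries. miR-30b-5p was at 310 ± 128 in PBS and 636 ± 325 in METH (log2 fold change 1.04, SE 0.59), and miR-30c-5p of the same family was at 3442 ± 508 and 5439 ± 1544 (log2 fold change 0.66, SE 0.47), above the PBS mean in 3 and in 4 of the 4 METH libraries. miR-19b-3p, a member of the growth-promoting miR-17-92 cluster, was at 65.9 ± 49.3 and 195 ± 157 (log2 fold change 1.57, SE 0.97), above the PBS mean in 3 of 4 METH libraries. None of these differences passed the test. edgeR called 0 of 166 miRNAs, higher or lower, at an adjusted p of 0.05, and 0 had an unadjusted p under 0.05, where 8.3 would be expected by chance. DESeq2 also called 0, with 2 at an unadjusted p under 0.05.

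The remaining miRNAs among the 10 with the smallest p did not pass either. The predicted miRNAs novel_639, novel_120, novel_121 and novel_35 had log2 fold changes of 1.42 (SE 0.97), 1.18 (SE 0.82), 0.88 (SE 0.60) and 0.80 (SE 0.64). miR-656, of the imprinted DLK1-DIO3 cluster, had 1.05 (SE 0.88) and novel_446 had −1.06 (SE 0.92). Without METH 2, the log2 fold changes of miR-30b-5p, miR-30c-5p and miR-19b-3p were 0.56, 0.24 and 0.86. Without METH 1, that of miR-122-5p was −3.19, against −1.96 without PBS 2 and −1.61 without both libraries numbered 4. That of novel_121 was 0.21 without METH 1, and that of novel_446 was −2.26 without METH 1 and −0.33 without PBS 1. Without METH 3, that of novel_639 was 0.57. Without PBS 4, those of novel_120, novel_35 and miR-656 were 1.88, 1.36 and 1.85, and novel_35 had 0.34 without METH 4 and miR-656 had 0.66 without PBS 3.

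The spread between libraries set the limit of this comparison. The common dispersion was 0.615, a biological coefficient of variation of 78.4%, and the median 95% interval reached 1.59 log2 units to either side of the estimate, or 3.01-fold. The interval excluded a 2-fold change for 0 miRNAs, a 4-fold change for 94 and an 8-fold change for 150 of the 166. With TMM scaling, 126 miRNAs had a log2 fold change above 0 and 40 below, with a median of 0.21. The split was 93 to 73 with DESeq2 size factors, 88 to 78 with upper quartile factors and 64 to 102 with total counts only, which moved the log2 fold changes by a median of −0.15, −0.16 and −0.35, so no general direction holds over the scalings.

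**Figure D3:**
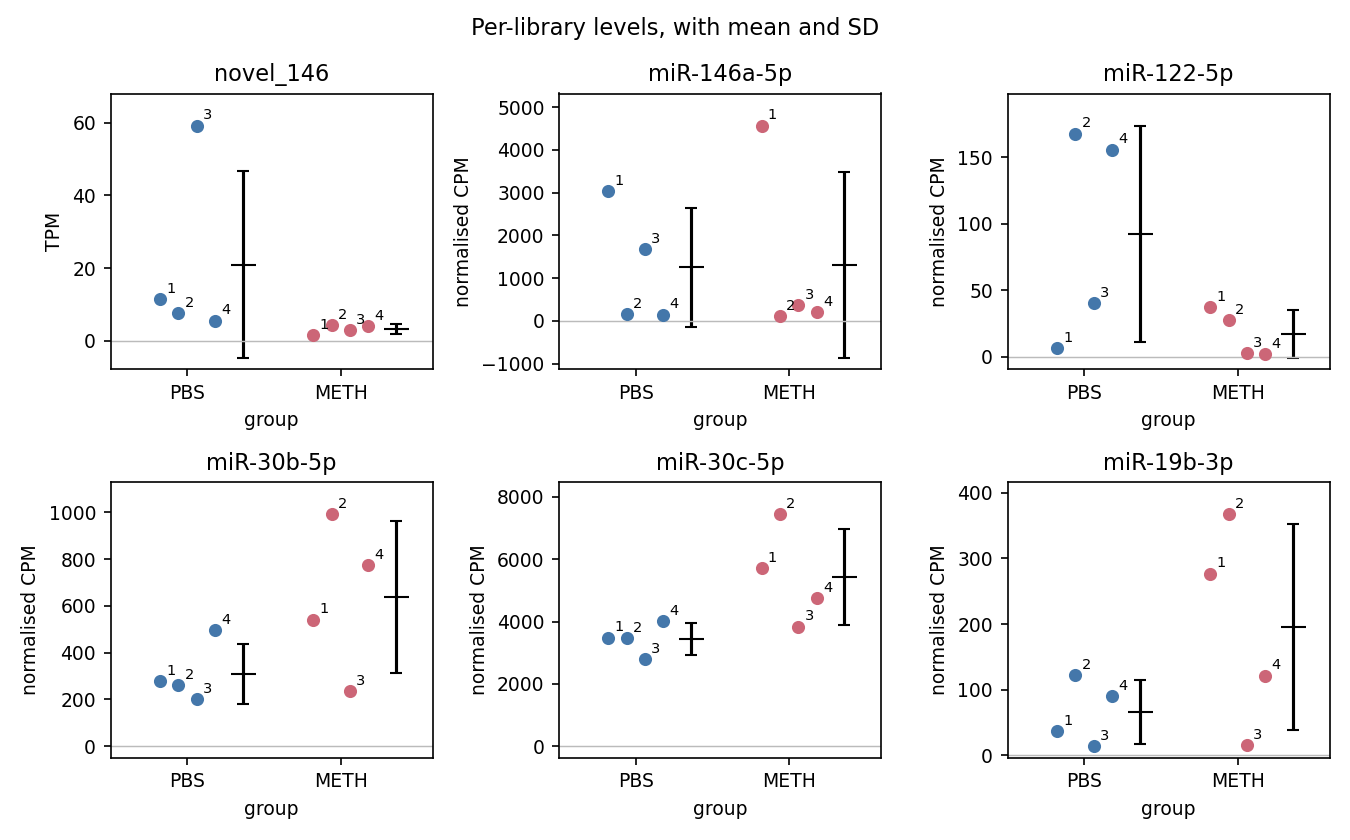
Level of 6 miRNAs in each library, as deposited TPM for novel_146 and as normalised CPM for the others, with 1 numbered point per library and the mean and SD (n = 4) in black. novel_146 lies between 5.59 and 59.2 TPM in PBS and between 1.56 and 4.41 TPM in METH, and the groups overlap for the 5 others.

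novel_146, the predicted miRNA of the series title, was lower in each of the 4 METH libraries than in any PBS library, at few reads. Its counts were 6, 6, 23 and 41 in PBS 1 to 4, and 1, 3, 1 and 27 in METH 1 to 4. These are 11.4, 7.70, 59.2 and 5.59 TPM in PBS and 1.56, 4.41, 2.95 and 4.03 TPM in METH. The difference of mean log2(TPM + 1) was −1.82 (METH minus PBS, exact two-sided permutation p = 0.0286, n = 4), the smallest p that 70 splits can give. Without METH 1 the difference was −1.60 (exact permutation p = 0.0857), and without METH 2, METH 3 or METH 4 it was −1.96, −1.81 and −1.92 (exact permutation p = 0.0571 each). These p count 3 or 2 of 35 splits, of which only the real one lay as low and the others differed as much in the opposite direction, so they do not show a smaller difference. This test of 1 miRNA was added after its values were seen, and how the study chose novel_146 is not given in the sources used here, so the result cannot be taken as independent evidence.

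novel_146 lay below the count filter, and across all 384 miRNAs its difference did not pass. With no filter, edgeR gave a log2 fold change of −1.88 (SE 0.93, 95% interval −3.82 to 0.07, adjusted p = 0.999), and DESeq2 gave −2.12 (SE 0.92, adjusted p = 0.999). Its p was the lowest of the DESeq2 fit (DESeq2 unadjusted p = 0.0220). With a mean count of at least 10 it was also the lowest (edgeR unadjusted p = 0.0329), and no adjusted p of that fit lay under 0.995. PBS 3 held 23 of the 35 PBS reads outside PBS 4, and without it the edgeR value was −1.22. In the deep libraries numbered 4, METH had 0.721 times the PBS level (exact 95% interval 0.426 to 1.20 for counting error). The only miRNA in the table with a miR-146 family name, miR-146a-5p, an inhibitor of inflammatory signalling, was at 1256 ± 1391 normalised CPM in PBS and 1313 ± 2174 in METH (log2 fold change 0.06, SE 1.24). Its estimate was −0.09 with DESeq2 size factors, −0.10 with upper quartile factors, −0.94 with total counts, −2.69 without METH 1, which held 4570, 0.89 without PBS 1, and 3.49 without PBS 1, PBS 3 and METH 3.

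The 4 neuron-enriched miRNAs tested had log2 fold changes above 0 with TMM, as did 126 of all 166 miRNAs, and none passed. The listed miR-124, miR-132, miR-137, miR-138, miR-153 and miR-212 matched none of the 384 miRNAs. The list therefore covers only part of its planned members. miR-129-5p was at 1814 ± 1495 normalised CPM in PBS and 4040 ± 6323 in METH (log2 fold change 1.15, SE 1.15), with 13466 in METH 3, and the value was −1.05 without METH 3 and 1.85 without PBS 1. miR-9-5p had 0.53 (SE 0.72; 0.16 without PBS 3 and 1.08 without PBS 1). miR-128, a brain-enriched miRNA, had 0.24 (SE 0.48; −0.14 with total counts, −0.16 without METH 1 and 0.44 without PBS 2), and miR-218-5p, an abundant motor neuron miRNA, had 0.02 (SE 0.81; −0.12 with DESeq2 size factors, −0.05 with upper quartile factors, −0.38 without PBS 3 and 0.93 without PBS 2). The list's median was 0.38, ranging from 0.06 without METH 1 (0.18 without METH 3) to 0.81 without PBS 2, its camera adjusted p was 0.679, and 0 members passed over all miRNAs or adjusted over the list alone.

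**Figure D4:**
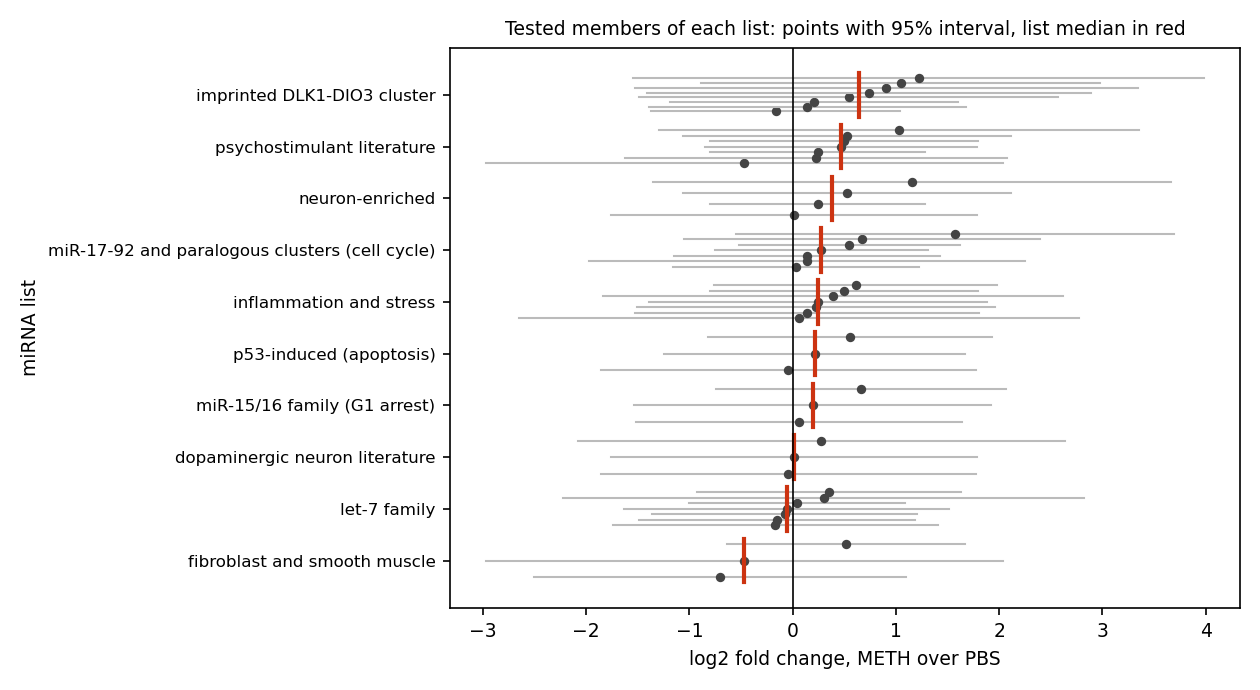
Log2 fold change (METH over PBS) of each tested member of the 10 lists with at least 3 tested members, as a point with its 95% interval and the list's median as a red bar. Medians run from −0.47 for the fibroblast and smooth muscle list, which is 0.38 without PBS 2, to 0.64 for the imprinted DLK1-DIO3 cluster, all member intervals include 0, and other scalings turn the medians of the miR-15/16 (0.19), dopaminergic (0.02) and miR-17-92 (0.28) lists below 0.

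Of the markers of other cell types, 7 were tested and none passed. Among astrocyte-associated miRNAs, miR-29b-3p had a log2 fold change of 1.03 (SE 1.06; 0.41 without METH 4 and 1.85 without PBS 4) and miR-29a-3p had 0.47 (SE 0.60; 0.03 without METH 4 and 0.98 without PBS 4). miR-29c-3p, below the filter, was at 3.01 ± 1.17 normalised CPM in PBS and 6.35 ± 0.830 in METH (n = 4), higher in each METH library than in any PBS library, but not so on TPM, with 1 to 5 reads in the libraries numbered 1 to 3 (edgeR with no filter 0.87, SE 0.94, adjusted p = 0.999). In the fibroblast and smooth muscle list, miR-199b-3p had 0.52 (SE 0.53; 0.29 without METH 2 and 0.83 without PBS 4), miR-143-3p had −0.47 (SE 1.14; −0.92 without METH 4 and 0.38 without PBS 2) and miR-10b-5p had −0.71 (SE 0.82; −0.30 without METH 4). Without METH 1 miR-10b-5p had −1.96, the lowest p of that fit (edgeR adjusted p = 0.995). That list's median was −0.47, with a camera adjusted p of 0.679, and ranged from −0.83 without PBS 3 to 0.38 without PBS 2. The leukocyte miRNA miR-155-5p had 0.14 (SE 0.76), and −0.08, −0.07 and −0.31 with DESeq2 size factors, upper quartile factors and total counts, −1.12 without METH 3 and 0.50 without METH 4. miR-142, restricted to blood-lineage cells, was below the filter, with 36 reads in METH 1 and at most 8 in any other library.

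Other markers were too few to test. The epithelial miR-200b-3p was at 236 normalised CPM in PBS 1 and 316 in METH 3, and at most 6.29 in the other 6 libraries. miR-200a-3p was at 106 in PBS 1 and 76.4 in METH 3 and at most 23.7 elsewhere, miR-200c-3p at 30.9 and 65.8 and at most 16.8 elsewhere, and miR-141-3p had 2 reads in PBS 4 and 0 elsewhere. The oligodendrocyte miRNA miR-219-5p had 2 reads in PBS 4, 4 in METH 4 and 0 in the other 6, where a count of 0 allows up to 8.84 TPM in the shallowest. The red cell miRNA miR-486-3p, below the filter, was at 10.8 ± 6.42 in PBS and 19.2 ± 24.3 in METH (n = 4; edgeR with no filter 0.44, SE 0.90, and −0.52 without METH 3). Endothelial and muscle list members were not analysed here, since 0 of the listed miRNAs matched them.

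For the cell cycle, the 7 tested members of the miR-17-92 and paralogous clusters all had log2 fold changes above 0 with TMM (median 0.28), 4 with DESeq2 size factors or upper quartile factors, and 3 with total counts (median −0.24). None passed over all miRNAs or adjusted over the list alone, and the camera adjusted p was 0.679. The median ranged from 0.11 without METH 2 to 0.51 without METH 4. Beside miR-19b-3p, miR-363-3p had 0.67 (SE 0.79; −0.63 without METH 1 and 1.10 without METH 4), miR-20a-5p had 0.55 (SE 0.49; 0.23 without METH 2) and miR-17-5p had 0.28 (SE 0.47; −0.24 with total counts and −0.08 without METH 2). In the miR-15/16 family, which can arrest cells in G1, miR-15a-5p had 0.66 (SE 0.64; 0.16 without METH 4), miR-15b-5p had 0.19 (SE 0.79; −0.35 with total counts, −0.82 without METH 3 and 0.55 without PBS 3) and miR-503 had 0.06 (SE 0.72; −0.37 with total counts, −0.71 without METH 3 and 0.42 without METH 4). This median of 0.19 was −0.01 with DESeq2 size factors, −0.02 with upper quartile factors, −0.35 with total counts, −0.19 without METH 3 and 0.42 without METH 4, and the camera adjusted p was 0.930. miR-424-5p, below the filter, was at 5.53 ± 3.8 normalised CPM in PBS and 15.9 ± 9.06 in METH (n = 4; edgeR with no filter 1.38, SE 0.91, adjusted p = 0.999, and 2.15 without PBS 4).

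For apoptosis, 3 of the p53-induced miRNAs were tested. miR-34a-5p, the best-known p53 target among miRNAs, was at 314 ± 100 normalised CPM in PBS and 462 ± 359 in METH (log2 fold change 0.56, SE 0.63), and at −0.10 without METH 4. miR-194-5p had 0.21 (SE 0.67; −0.16 without METH 4 and 0.69 without PBS 4) and miR-34c-5p had −0.04 (SE 0.83; −0.45 without PBS 3 and 0.25 without PBS 1), and miR-192-5p, below the filter, was at 21.3 ± 18.2 and 12.4 ± 4.43 (n = 4; edgeR with no filter −0.84, SE 0.92, and −0.41 without PBS 4). The list's median of 0.21 was −0.08 without PBS 3, −0.08 without METH 2, −0.20 without METH 4, 0.69 without PBS 4 and −0.12 without PBS 1, PBS 3 and METH 3, and its camera adjusted p was 0.679. Of the 7 let-7 family members tested, which promote differentiation, 3 were above 0 and 4 below. let-7i-5p had −0.15 (SE 0.61; −0.46 without METH 1 and 0.52 without PBS 2), miR-98-5p had 0.35 (SE 0.58; −0.04 without METH 2 and 0.60 without PBS 2), let-7a-3p had 0.30 (SE 1.15; −0.14 without METH 2 and 1.17 without PBS 2) and let-7a-5p had −0.17 (SE 0.72; −0.53 without METH 2 and 0.42 without PBS 2). The let-7 median was −0.06 (−0.24 without METH 2, 0.42 without PBS 2, 0.02 without METH 3 and 0.11 without METH 4) and the mean 0.03, camera placed the list lower (adjusted p = 0.679) and fry higher (adjusted p = 0.930).

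The 7 inflammation and stress miRNAs were all above 0 with TMM (median 0.24), 5 with DESeq2 size factors or upper quartile factors and 4 with total counts, and none passed (camera adjusted p = 0.930). Their median ranged from 0.05 without METH 2 to 0.57 without PBS 1, and was −0.13 without PBS 1, PBS 3 and METH 3. miR-221-3p and miR-222-3p, a pair from 1 cluster that promotes cell division, had 0.61 (SE 0.63) and 0.50 (SE 0.59), and both were −0.24 without METH 3. miR-21-5p had 0.39 (SE 1.02; −0.02 without PBS 3, 0.91 without PBS 4 and −0.15 without PBS 1, PBS 3 and METH 3), and the hypoxia miRNA miR-210 had 0.24 (SE 0.75; −0.23 with total counts and 0.88 without PBS 1). Of the 7 psychostimulant literature miRNAs tested, 6 were above 0 with TMM and 4 with total counts, with a median of 0.47 and a camera adjusted p of 0.570. This median was 0.15 without METH 3, 0.16 without PBS 3 and 0.10 without PBS 1, PBS 3 and METH 3. Of the 3 dopaminergic neuron literature miRNAs tested, miR-7-5p, which represses alpha-synuclein, had 0.28 (SE 1.07; −1.09 without METH 1 and 2.16 without PBS 2). That list's median was 0.02, with a camera adjusted p of 0.679, and was −0.12 with DESeq2 size factors and −0.05 with upper quartile factors. It was between −0.38 and −0.08 without PBS 1, PBS 3, METH 1, METH 2 or METH 4 in turn, 0.25 without METH 3 and 0.93 without PBS 2 (camera adjusted p = 0.297).

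The imprinted DLK1-DIO3 cluster, a large neuronal miRNA cluster, had the lowest camera p of the 10 lists tested. Of its 8 tested members, 7 had log2 fold changes above 0 with TMM, where 126 of all 166 miRNAs did. The count was 6 with DESeq2 size factors and 5 with upper quartile factors or total counts. Among the 7 were miR-539-3p with 1.22 (SE 1.26; 0.77 without PBS 3 and 2.38 without PBS 4), miR-656 with 1.05 (SE 0.88; 1.85 without PBS 4), miR-369-3p with 0.91 (SE 1.11; −0.26 without METH 4 and 2.82 without PBS 4) and miR-381-3p with 0.74 (SE 0.98; 0.07 without METH 4 and 1.52 without PBS 4). The median was 0.64 and the camera adjusted p was 0.570 (adjusted p = 0.868 with an estimated correlation), so the list did not pass. Without PBS 4 its median was 1.51 and its camera adjusted p 0.0295 (adjusted p = 0.907 with an estimated correlation), and without METH 2 they were 0.80 and 0.0261 (adjusted p = 0.639 with an estimated correlation). The median was 0.12 without METH 4 and 0.14 without PBS 1, PBS 3 and METH 3. Over the 10 lists, 0 passed with camera, 0 with an estimated correlation and 0 with fry, and in each list 0 members passed over all miRNAs or adjusted over the list alone.

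No difference between predicted and known miRNAs as sets was detected. Of 53 predicted miRNAs tested, 37 had log2 fold changes above 0 and 16 below (median 0.17), against 89 and 24 of the 113 known ones (median 0.23; camera p = 0.346 in limma, and p = 0.576 with an estimated correlation). Without PBS 2 the difference of the medians (predicted minus known) was −0.25 and the camera p was 0.0114 with the preset correlation. An estimated correlation was not run for this fit. The PBS group then holds PBS 4 beside PBS 1 and PBS 3, which stood apart. Both arms passed the filter for let-7a and miR-1306 only. The log2 ratio of the 5p to the 3p arm was 0.24 ± 1.57 in PBS and −0.50 ± 1.62 in METH for let-7a, and 0.60 ± 1.5 and 0.48 ± 1.28 for miR-1306 (n = 4 each), with a limma adjusted p of 0.909 for both. The limma variance was shared over let-7a and miR-1306 only. Over all libraries let-7a had 847 reads from the 5p arm and 1880 from the 3p arm. Reads shared with other let-7 members cannot be separated, so its ratio may not reflect arm choice alone.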

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

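The tests of METH treatment, cell type shares and GC content, and the use of edgeR without PBS 3 to judge PBS 3 as a source for novel_146, were chosen only after the pattern they bear on was seen. Over the 5 library measures and the 56 named miRNAs in each group of 4 libraries, 122 sets of values were examined for a single library far from its group, on the natural scale for library measures and on log2(normalised CPM + 1) for miRNAs. Of these, 15 stood out, where chance gives 1 in 20, or 6.1. The sets are not independent. Many of the 15 fall on METH 3 or on the depth of PBS 4 and METH 4. A miRNA with reads in 1 library of its group alone is flagged by necessity. The 15 therefore do not count separate events, and their excess over 6.1 cannot be read as such.

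Total counts stood out in PBS 4 (7334789) and METH 4 (6702946), as did the number of miRNAs detected there, 354 and 342 against 257 to 264 in the other libraries. In METH 3 the share of predicted miRNAs was 28.1%, against 4.48% to 8.18% in the other METH libraries. PBS 1 and PBS 3 held 23.4% and 22.3%, so a high share was not particular to METH 3. METH 3 was also low in miR-218-5p (495 normalised CPM), miR-143-3p (1117), miR-20a-5p (572), miR-98-5p (548) and let-7a-3p (5.27), where the other METH libraries had at least 1683, 24319, 1298, 1724 and 127. miR-143-3p was low in PBS 1 and PBS 3 too, the libraries that stood apart together with METH 3. METH 1 stood out with miR-142 at 75.5, against 0 to 0.942 in the other METH libraries, and with miR-210 at 10.48, against 45.03 to 54.6. miR-219-5p was detected within its group in PBS 4 alone (0.322) and METH 4 alone (0.754), and miR-141-3p in PBS 4 alone (0.322), each at 2 to 4 reads in the deepest libraries.

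PBS 1, PBS 3 and METH 3 stood apart from the other 5 libraries, with a gap of 0.634 of the range on the first principal component. The gap was 0.610 with all libraries thinned to the smallest total and 0.621 without miR-21-5p. This argues against the number of reads counted and against miR-21-5p as the whole cause. PBS 1, PBS 3 and METH 3 also had the lowest totals (526031, 388419 and 339243, against 642982 or more in the others). Thinning cannot exclude differences in RNA quality or library preparation that a low total may mark. Libraries of both groups on either side (exact permutation p = 0.943) argue against METH. Ratios of miRNAs from 1 primary transcript varied less over the libraries (median SD 0.93 log2 over 18 pairs) than those of matched random pairs (1.35, at percentile 0.66 of 10000 random sets), but more than counting error gives (SD 0.135), and in 9 of the 18 the ratios in PBS 1, PBS 3 and METH 3 lay outside the range of the other 5 libraries. These 3 libraries were picked out on the same data, and the share was not taken for random pairs, so the 9 add no separate support. Different shares of cell types alone would keep ratios within 1 transcript close if they are alike in every cell type, which was not tested. The 3 miR-17-92 pairs, all among these 9, did not keep them close (median range 5.00, with paralogous clusters encoding some of them). All 3 pairs hold miR-92a-3p, so they are not independent of each other and may reflect that 1 miRNA. For the 15 pairs outside miR-17-92, with a median range of 2.12 and 6 of them among the 9, shares of cell types may account for part of the pattern and cannot be told apart from GC content, since the table used here holds 0 miRNA sequences, and differences in RNA quality or library preparation, for which no label was used here, were not tested.

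novel_146 was lower in each METH library than in each PBS library. In libraries 1 to 3, PBS held 35 pooled reads and METH 5 (exact p = 1.43e-06), and PBS 3 held 23 of the 35. This argues against counting error as the whole cause of that pooled difference. In the libraries numbered 4 (41 and 27 reads), counting error was not excluded (exact p = 0.225). A pooled test does not bear on the separation of single libraries at few reads, so counting error stays open for it. Without PBS 3 the pooled reads (12 and 5, exact p = 0.0472) met the bound of 0.05 set beforehand for excluding PBS 3 as the source, but that bound was wrong because it left out the spread between libraries, with which edgeR gave −1.22 (p = 0.274), so this stays open. Selection among many miRNAs stays open, since 1 of the 193 miRNAs detected in all libraries separated the groups completely on TPM, where chance gives 5.51. An effect of METH on novel_146 therefore remains a hypothesis that these libraries may not settle.

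With 0 called miRNAs between METH and PBS in edgeR (0 at an unadjusted p under 0.05, DESeq2 0 with 2), each of the 35 splits of the 8 libraries into 4 and 4 gives at least as many by necessity, so chance is not excluded and the splits say nothing more about it. The highest other split gave 22 (PBS 1, PBS 3, METH 2 and METH 3 against the rest) and 1 further split gave 7, both with PBS 1, PBS 3 and METH 3 on one side. Of the 5 splits with these libraries on one side, 3 gave 0 calls. These libraries were already seen to stand apart, so the calls restate that structure of the samples and add no support for it.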

How the results depend on the processing

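The novel_146 test, the fits without the libraries numbered 4 or without PBS 1, PBS 3 and METH 3, and the surrogate variable were chosen after the data were seen. The edgeR count of 0 called miRNAs held in each of the 25 alternatives, with 0 to 10 miRNAs at an unadjusted p under 0.05 and a lowest adjusted p of 0.866 (without METH 3). The 56 named miRNAs had 891 alternative values, none past the threshold (lowest adjusted p 0.618), with 119 changes of sign in 32 of them and none in 24. The list medians changed sign in 23 of 159 values, in 7 of 10 lists. With 1 library left out, 0 to 1 lists passed camera. That list was the imprinted DLK1-DIO3 cluster, without PBS 4 (adjusted p 0.0295, and 0.907 with an estimated correlation) or without METH 2 (adjusted p 0.0261, and 0.639 with an estimated correlation). The cause was not tested, and 0 passed in the other alternatives run. The predicted minus known median log2 fold change, −0.0597, ranged from −0.253 (camera p 0.0114 with the preset correlation alone, without PBS 2) to 0.0690 (without METH 2), and was 0.0625 without PBS 1. The METH minus PBS difference in total count, −165594, ranged from −1702760 without METH 4 to 1526990 without PBS 4, since these hold most reads, and was also above 0 without METH 1, METH 2 or METH 3. The difference in the share of predicted miRNAs, −2.38 percentage points, ranged from −7.86 without METH 3 to 0.745 without PBS 1, and was also above 0 without PBS 3 or METH 1. The novel_146 difference of mean log2(TPM + 1), −1.82, ranged from −2.20 without PBS 4 to −1.13 without PBS 3, with an exact permutation p of 0.0857 without METH 1 (difference −1.60), 0.0571 without METH 2, METH 3 or METH 4 (−1.96, −1.81 and −1.92) and 0.0286 without any 1 PBS library. The groups stayed separated, and the p rose through 1 or 2 of 35 splits with as large a difference in the opposite direction. The difference in the top share, 8.24 percentage points, ranged from 2.45 without PBS 3 to 17.3 without METH 3, and that in the effective number, −4.64, from −8.95 without METH 3 to −0.686 without PBS 3. Arm ratios gave 0 calls in all alternatives, although a mean count of at least 50 left 1 hairpin.

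The replicate numbers were not taken to pair the samples, since no label says what a number shares. Deviations of same-numbered libraries correlated at −0.25, 0.54, 0.77 and 0.89 for numbers 1 to 4. The libraries numbered 2 to 4 each correlated best with their own number, PBS 1 with METH 3 (0.77) and METH 1 with PBS 2 (0.53), so a shared origin of some numbers stays open. Some of these matches were near ties. METH 3 correlated at 0.772 with PBS 3 and 0.770 with PBS 1, the libraries that stood apart with it. PBS 2 correlated at 0.543 with METH 2 and 0.531 with METH 1. The match was clearest for number 4, whose libraries were by far the deepest (7334789 and 6702946 reads). For these, shared depth cannot be told apart from a shared origin. With a replicate block, 0 miRNAs, 0 lists and 0 arm ratios were called, with 2 miRNAs at an unadjusted p under 0.05, and the predicted minus known median was −0.07.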

Other observations

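The miRNAs below were chosen after their values were seen. miR-92a-3p, of the miR-17-92 cluster, was at 17726 normalised CPM in PBS 1, 24195 in PBS 3 and 43493 in METH 3, and between 3289 and 4249 in the other 5 libraries. Its cluster partner miR-19b-3p went the other way, at 37.4, 14.0 and 15.8 in those 3 libraries and between 89.8 and 368 in the others, so that the log2 ratio of the first to the second, on log2 CPM with a prior count, ran from 3.44 in METH 2 to 11.33 in METH 3. miR-32-5p had 0 reads in PBS 1, PBS 3 and METH 3 and between 18 and 798 reads in the others. miR-101, which represses EZH2, was at 92.8, 43.4 and 44.8 normalised CPM in them and between 917 and 1927 in the others. miR-125b-5p, abundant in neural cells, was at 46557, 35492 and 75797 in them and between 11520 and 20869 in the others.

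Some libraries of different groups resembled each other more than their own group. Over the 166 tested miRNAs, which are not independent replicates, Spearman's rho was 0.985 between PBS 4 and METH 4, the deepest libraries. It was 0.966 between PBS 1 and METH 3. Within PBS it was as low as 0.781 (PBS 1 and PBS 4). On the second principal component, PBS 2 (7.40) and METH 1 (8.23) lay together, as did PBS 4 (−6.55) and METH 4 (−7.99). PBS 2 and METH 1 also had the highest miR-7-5p, 29507 and 31805 normalised CPM, against 1725 to 9733 in the other 6 libraries.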
